A study of Rattus norvegicus with 9 samples.

How the data were processed

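RNA was measured in the cerebral cortex of Hsd:Sprague Dawley rat pups on postnatal day 4, with 1 Affymetrix Rat Genome 230 2.0 array per pup. Per the labels' protocols, 100 ng of total RNA per sample was labelled with the 3' IVT Express method, with 16 hours of in vitro transcription. Per the submitters' processing notes, the probe intensities were processed with the affy package and the robust multi-array average (RMA), which corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. No versions are named. The deposited values are log2 RMA intensities, 1 per probe set and array, for 31099 probe sets on 9 arrays. A difference of 1 on this scale is a doubling of intensity. Quantile normalization gives all arrays the same overall distribution, so a change in total RNA per cell would not be seen. RMA values carry no detection call, and their differences are compressed near background.

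The labels place 3 arrays in each of 3 groups: control diet, 750 ppm and 2500 ppm of 4-methylimidazole (4-MeI) in the diet. Each pup came from a different litter, so the p-values of single probe sets measure the spread between pups of different litters. The number of arrays limits the precision. No pooling, sex of the pups or array batch is stated.

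The 57 AFFX control probe sets were set aside. The 30% of the remaining probe sets with the lowest mean over all 9 arrays were also left out. That filter removed 9313 probe sets with a mean under a log2 value of 6.35 and left 21729. A linear model with 1 mean per group was fitted to all 9 arrays in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 loaded. Variances were empirical Bayes (prior degrees of freedom 3.25, median residual SD 0.105). In the alternative with a replicate block, the replicate number was a fixed term. The contrasts were 750 ppm minus control, 2500 ppm minus control and 2500 ppm minus 750 ppm. A separate model took the dietary concentration as a number, per 1000 ppm. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05, and all tests were two-sided. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so single values were tested in the limma model.

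Gene names came from the platform annotation, with symbols checked through the Entrez gene identifier against a gene table of assembly GRCr8. Of the probe sets without controls, 20826 carried 1 symbol, 436 several and 9780 none. Positions given are those of the gene in GRCr8, not of the probes. The values of named genes are those of the probe set given. They were chosen by a rule. Per contrast it took the 12 highest and the 12 lowest log2 changes among probe sets past the threshold, with 1 symbol and with no overlap between the arrays of both groups. Where fewer than 20 genes qualified, the list was filled to 20 with the smallest unadjusted p among genes with an absolute log2 change of at least 0.5 and no overlap. Up to 4 members of each gene list described were named by their p.

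Gene lists were tested with camera in limma, at a preset correlation between genes of 0.01, on the probe set with the highest mean for each of 11606 genes. There were 48 lists for cell types, neighbouring brain regions, receptors, channels, stress responses and metabolism, and 46 had at least 5 measured genes. The lists for blood cells and for sex-linked genes had fewer and were not tested. At the preset correlation, the camera p rests on the spread of the test statistics between genes. It does not measure the spread between pups. Camera was repeated with a correlation estimated from the data, and fry was run beside it. Members of the lists are given with p-values adjusted over the 11606 genes, and counts are also given adjusted over the list alone. The groups, contrasts, tests, these 48 gene lists and the naming rule were fixed before the data were examined.

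The model was tested on simulated data before use. In 21729 simulated probe sets, it called 99% of 100 changed 2-fold and 88% of 100 changed 1.5-fold at 2500 ppm, with 10 unchanged probe sets called and 0 calls of the wrong sign. The noise was drawn independently for each probe set, without variation shared between genes. These shares therefore do not carry over to arrays that differ in tissue content.

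The alternatives tried were other filters on dim probe sets, median-centring, a second quantile normalization, the replicate number as a block, another variance model, array weights, fits of only the groups compared, other thresholds, 1 probe set per gene, other probe sets of the named genes, other ways to test lists, and leaving out each array. Alternatives chosen after seeing the data were leaving out 2 arrays together and taking the mean of a tissue list as a covariate. Probe sets with several symbols or none were counted but not named.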

Results

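The series concerns 4-methylimidazole (4-MeI), a small nitrogen heterocycle that forms when foods brown and that occurs in some caramel colourings. Its title gives exposure during gestation and maternal seizures as the setting in which the cortex of the offspring was profiled. Rats received the compound in the diet through successive generations, and the F2b pups were sampled on postnatal day 4, 1 pup per litter. Cortex from 3 control pups, 3 pups of the 750 ppm group and 3 pups of the 2500 ppm group was profiled on 9 arrays. The labels do not say which dams had seizures.

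The 9 arrays had closely similar intensity, with median log2 values between 7.67 and 7.71, and the lowest correlation of an array with another of its own group was 0.988. The first principal component held 35.6% of the variance and the second 23.1%. Control replicate 3 stood apart from its group, with a first score of -25.2 against -8.64 and -9.47 in the other controls. The 750 ppm replicate 3 scored 14.98 against -5.97 and -11.3 in its group. The 2500 ppm arrays scored 18.8, 10.3 and 16.4, so 750 ppm replicate 3 lay within their range. Its highest correlation, 0.993, was with an array of another group. Marker genes of tissues that border the cortex differed between arrays. The mean of 15 striatal genes, relative to the mean over all arrays, was -0.90 in 750 ppm replicate 3 against 0.61 and 0.54 in the other 750 ppm arrays. It was -0.98, -0.051 and -0.58 in the 2500 ppm arrays and 0.66, 0.28 and 0.42 in the controls. The mean of 18 meningeal genes was -0.14, -0.59 and -1.11 in the controls, and that of 10 choroid plexus and ependymal genes was 1.20, 1.10 and 0.21 in the 2500 ppm arrays.

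**Figure D1:**
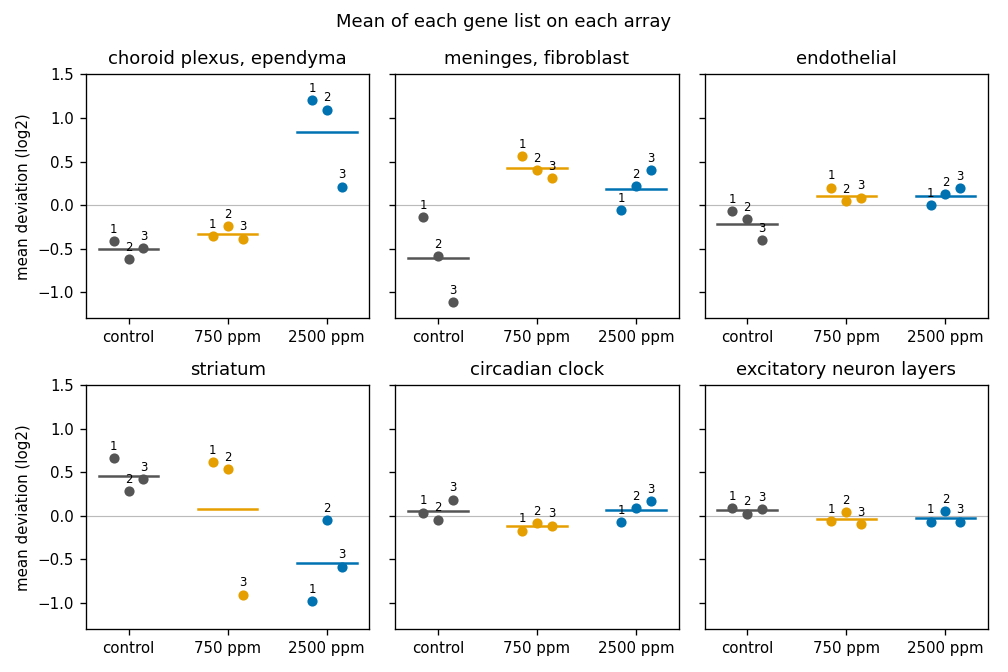
Mean of 6 gene lists on each array, as the average log2 deviation of their genes from the mean over the 9 arrays; numbers mark the replicates and lines the group means. The choroid plexus list reached 1.20 in a 2500 ppm array, the meningeal list was lowest in control replicate 3 at -1.11, and the striatal list was at -0.90 in 750 ppm replicate 3.

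The comparison of 2500 ppm with control asked which transcripts differed in the cortex of pups at the higher dietary concentration. Ttr, which encodes the thyroid hormone carrier transthyretin made by the choroid plexus, rose by 5.67 on the log2 scale (SE 0.62, n = 3 against 3, adjusted p = 0.0135). Its mean went from 7.74 (SD 0.42) in controls to 13.40 (SD 1.17) at 2500 ppm, with 9.07 (SD 1.06) at 750 ppm. Nts, the neurotensin precursor, rose by 1.94 (SE 0.32, adjusted p = 0.0378), and Sult1a1, a sulfotransferase of phenols and drugs, rose by 1.22 (SE 0.19, adjusted p = 0.0295). C1ql3, a secreted synaptic protein, fell by 1.42 (SE 0.10, adjusted p = 0.00304) on 1 of its probe sets, while another probe set of the gene gave 0.12 with an adjusted p of 0.412. Tac1, the precursor of substance P, fell by 1.10 (SE 0.14, adjusted p = 0.0185).

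Other named genes fell on arrays where a list of 15 striatal genes had a median of -1.10 against control. Cdh13, a cadherin without a cytoplasmic domain, fell by 0.97 (SE 0.10, adjusted p = 0.0131), and both of its other probe sets also passed. Cdh22, another cadherin, fell by 1.18, while its other probe set was at -0.062 with an adjusted p of 0.868. The synaptic vesicle protein gene Sv2b fell by 0.98 (adjusted p = 0.0324), from 11.93 (SD 0.19) to 10.95 (SD 0.11), and was at -0.48 (adjusted p = 0.0984) on another probe set. The synaptotagmin gene Syt6 fell by 1.01, and Meis2, a homeobox transcription factor of the developing forebrain, fell by 0.94 (SE 0.10, adjusted p = 0.0135) from a high mean of 13.11 (SD 0.10). Luzp2 fell by 0.97 (SE 0.09, adjusted p = 0.0115) on 1 probe set and was at -0.16 with an adjusted p of 0.374 on another. Plce1, Rasgef1c, Prrc2c and Rnd3 fell by 0.83 to 0.99, but other probe sets of Prrc2c (-0.28 to -0.62) and Rnd3 (-0.62 and -0.64) did not pass. Among the genes that rose were the collagen gene Col8a2 (1.96, SE 0.31), the keratin gene Krt8 (1.34), the matrix proteoglycan gene Fmod (1.12), the drug and cation exporter gene Slc47a1 (0.99) and the adenosine deaminase gene Ada (0.99). Ap1s3 (1.25), Tshz2 (1.19), Mustn1 (0.98) and Serpinb1a (0.98, with 0.29 and an adjusted p of 0.188 on another probe set) rose as well, and the 24 genes of the rule had adjusted p between 0.00304 and 0.0447. On the GRCr8 assembly, Ttr lies on chromosome 18 from 12216684 to 12225972, C1ql3 on chromosome 17 from 81028418 to 81038244, and Tac1 on chromosome 4 from 36645344 to 36653548.

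**Figure D2:**
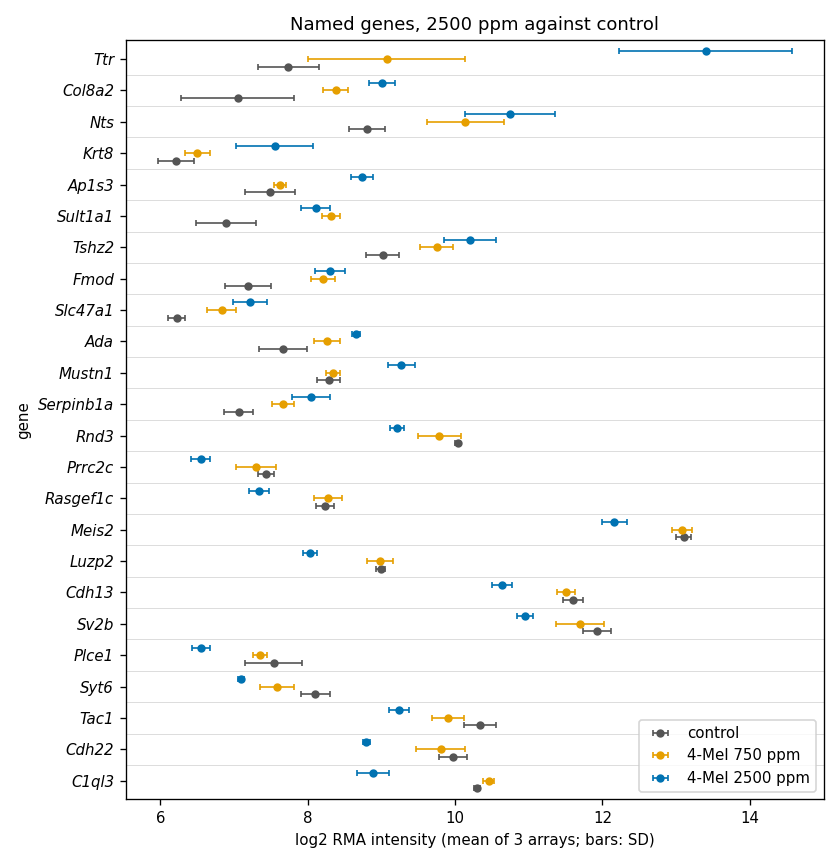
Group means of the log2 RMA intensity of the 24 genes named for 2500 ppm against control, with the gene on the vertical axis and bars of 1 SD over 3 arrays. Ttr went from 7.74 in controls to 13.40 at 2500 ppm, and C1ql3 from 10.30 to 8.88.

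In all, 149 probe sets passed at 2500 ppm, 61 higher and 88 lower, and they carried 94 named genes, 41 higher and 53 lower. At an unadjusted p under 0.05, 3478 probe sets differed, against 1086 expected by chance. The split of calls depended on the scaling, with 91 higher and 75 lower after median-centring and 74 higher and 71 lower after a second quantile normalization, and on the arrays fitted, with 103 higher and 378 lower when only the groups compared were fitted. The count went to 14 without control replicate 2, 32 without control replicate 3, and 25, 9 and 57 without the 2500 ppm replicates 1, 2 and 3, and to 234 and 466 without the 750 ppm replicates 2 and 3. Without both control replicate 3 and 750 ppm replicate 3, chosen after seeing the data, it was 263. Only C1ql3, Cdh13 and Luzp2, of the 24 named genes, on the probe sets named, passed each time 1 array was left out, and 4 of the 24 passed without 2500 ppm replicate 2, 6 without control replicate 2, 8 and 13 without 2500 ppm replicates 1 and 3, 11 and 18 without control replicates 3 and 1, and 22 without 750 ppm replicate 1.

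Genes of tissues that line the brain were higher at 2500 ppm. Of 10 measured choroid plexus and ependymal genes, 9 were higher, with a median of 0.56 and a mean of 1.35, and 8 passed adjusted over the list alone (1 over all genes tested). Sostdc1, a secreted Wnt and BMP antagonist, was 3.04 higher (SE 0.57, adjusted p = 0.0613), and the folate receptor gene Folr1 was 1.83 higher (SE 0.47, adjusted p = 0.125). Camera gave the list an adjusted p of 3.96e-06, and an adjusted p = 0.404 with an estimated correlation. All 18 meningeal and fibroblast genes were higher, with a median of 0.83 (0.53 without control replicate 3); 15 passed adjusted over the list alone and 1 over all genes tested (camera adjusted p = 6.1e-11, and adjusted p = 0.404 with an estimated correlation). That gene was Aldh1a2, which encodes an enzyme of retinoic acid synthesis, up by 0.71 (SE 0.09, adjusted p = 0.0173). The growth factor gene Igf2 was 1.21 higher (SE 0.25, adjusted p = 0.0777) and Ogn 1.39 higher (SE 0.31, adjusted p = 0.0903).

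Vascular, matrix and detoxification genes were also higher at 2500 ppm, in the comparison in which the meningeal list had a median of 0.83. All 17 endothelial genes were higher, with a median of 0.28, and 6 passed adjusted over the list alone (0 over all genes tested), among them Slco1a4 at 0.49 and Emcn at 0.84. Their camera adjusted p was 8.29e-07, with an adjusted p = 0.404 with an estimated correlation. Of 29 extracellular matrix genes, 8 passed higher and 1 lower adjusted over the list alone, and the gelatinase gene Mmp2 rose by 0.96 (SE 0.12, adjusted p = 0.0173) over all genes tested. The list had a median of 0.16, a camera adjusted p of 0.00456, and an adjusted p = 0.404 with an estimated correlation. Of 14 genes of xenobiotic metabolism, 12 were higher, with a median of 0.15 (0.24 without control replicate 1) and a mean of 0.40, and 4 passed adjusted over the list alone. Cyp1b1, a cytochrome P450 of aromatic compounds and steroids, rose by 0.92 (SE 0.14, adjusted p = 0.0322). The glutathione transferase gene Gsta1 was 1.87 higher (SE 0.36, adjusted p = 0.0647) and the epoxide hydrolase gene Ephx1 0.40 higher (SE 0.08, adjusted p = 0.0703). This list had a camera adjusted p of 0.000567, an adjusted p = 0.404 with an estimated correlation, and a fry adjusted p of 0.0204. All 17 microglial and macrophage genes were higher, with a median of 0.15 and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.0034, and adjusted p = 0.404 with an estimated correlation).

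Smaller shifts were seen for 13 pericyte and smooth muscle genes (median 0.16, 1 passing adjusted over the list alone, camera adjusted p = 0.015) and for 21 genes of cholesterol synthesis (median 0.19, 0 passing, camera adjusted p = 0.0147). With an estimated correlation, their adjusted p was 0.404 and 0.740. The pericyte call was lost without control replicate 3 (adjusted p = 0.0952) and without 2500 ppm replicate 3 (adjusted p = 0.0582). The cholesterol median was 0.34 without control replicate 2, and its call was lost without control replicate 3 (median 0.041, adjusted p = 0.833), 2500 ppm replicate 1 (adjusted p = 0.0926) and 2500 ppm replicate 3 (adjusted p = 0.0582).

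Striatal genes were lower at 2500 ppm. All 15 measured members were lower, with a median of -1.10, and 3 passed adjusted over the list alone against 1, Tac1, over all genes tested. The dopamine receptor genes Drd2 and Drd1 differed by -1.22 (SE 0.28, adjusted p = 0.0968) and -1.32 (SE 0.45, adjusted p = 0.214), and the phosphodiesterase gene Pde10a by -0.59 (SE 0.17, adjusted p = 0.159). Camera gave an adjusted p of 1.16e-07, and an adjusted p = 0.404 with an estimated correlation. Markers of cortical excitatory layers had a median of -0.12, with 9 of 17 lower, 2 higher and 6 lower at an unadjusted p under 0.05, a camera adjusted p of 0.364 and a fry mixed adjusted p of 0.00658, which tests for change in either direction. All 30 cytosolic ribosomal protein genes were lower by a small amount, with a median of -0.063 (-0.039 without 2500 ppm replicate 3) and 0 members past the threshold adjusted over the list alone (camera adjusted p = 0.000145, and adjusted p = 0.523 with an estimated correlation).

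The lists of channels, receptors and activity genes described here did not pass camera at 2500 ppm, but single members passed. The potassium channel gene Kcna4 fell by 0.49 (SE 0.06, adjusted p = 0.0220), and 4 of 27 potassium channel genes were lower adjusted over the list alone (median 0.024, mean -0.062, camera adjusted p = 0.202). Of 16 ionotropic glutamate receptor genes, 2 were lower adjusted over the list alone: the kainate receptor gene Grik2 (-0.91, SE 0.17, adjusted p = 0.0613) and the AMPA receptor gene Gria1 (-0.54, SE 0.10, adjusted p = 0.0647), with a camera adjusted p of 0.130. Scn3a, a sodium channel of immature neurons, differed by -0.47 (SE 0.10, adjusted p = 0.0891) and was the 1 of 10 sodium channel genes to pass adjusted over the list alone (camera adjusted p = 0.130). None of 11 GABA-A and GABA-B receptor genes passed by either adjustment (1 at an unadjusted p under 0.05, camera adjusted p = 0.380), and Gabra2 differed by -0.53 (SE 0.18, adjusted p = 0.209). Of 19 immediate early genes 0 passed, with 4 at an unadjusted p under 0.05 and a camera adjusted p of 0.165. Fos differed by -1.13 (SE 0.56, adjusted p = 0.371) and Bdnf by -0.43 (SE 0.14, adjusted p = 0.206). Among 20 neuropeptide genes, Tac1 fell and Nts rose over all genes tested, and the peptide gene Adcyap1 passed adjusted over the list alone at 0.53 (SE 0.10). That list had a median of 0.012, a mean of -0.11 and a camera adjusted p of 0.881. Of 17 genes of thyroid hormone transport and response, 2 were higher and 2 lower adjusted over the list alone, with Ttr and Nrgn (0.42, SE 0.09) on one side and Itih3 (-0.89, SE 0.16) and Camk4 (-0.43, SE 0.10) on the other. Klf9, a direct target of the thyroid hormone receptor, was at 0.19 (SE 0.14, adjusted p = 0.530), and the camera adjusted p was 0.924.

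The comparison of 750 ppm with control asked whether the lower concentration changed the cortex. Cplx3, which encodes a complexin that regulates release of synaptic vesicles, fell by 0.90 (SE 0.087, n = 3 against 3, adjusted p = 0.0310), from 8.22 (SD 0.13) to 7.32 (SD 0.14), while its mean at 2500 ppm was 8.35 (SD 0.024). It lies on chromosome 8 of GRCr8 from 66899438 to 66906200. The other probe set that passed has no gene symbol in the annotation and fell by 1.59. The other genes named here had the next smallest p and missed the adjusted threshold. Aldh1a2 was 0.75 higher (SE 0.089, adjusted p = 0.0858), Sult1a1 1.42 higher (SE 0.19, adjusted p = 0.145), and 17 more had an adjusted p of 0.201. These included the retinoic acid binding protein gene Crabp2 at 1.18 (SE 0.19), Cyp1b1 at 0.88 (SE 0.14), the anion transporter genes Slco1a4 at 0.76 and Slco2a1 at 0.56, Slc13a4 at 1.42, Slc6a13 at 1.42, Fmod at 1.02, Adh1c at 0.85, Vamp5 at 0.91, Pcolce at 0.76, Omd at 0.55, Olfml1 at 0.51, Col6a1 at 0.54 and Dmrtc1c1 at 0.89. Of those below control, Dcx, a microtubule protein of migrating neurons, was at -0.52 (SE 0.10), Cit at -0.59 and Ccdc191 at -0.50. Other probe sets of Adh1c, Slco2a1 and Dcx were at 0.060, 0.096 and -0.016.

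At 750 ppm, 2 probe sets passed, both lower, against 2202 at an unadjusted p under 0.05, 1253 higher and 949 lower, and 1086 expected by chance. With array weights 205 were higher and 135 lower, and an unadjusted p under 0.05 with a fold of at least 1.5 gave 181 higher and 51 lower. The call of Cplx3 was lost without control replicates 2 and 3 and without each 2500 ppm array in turn, with an adjusted p of at most 0.132. The count was 0 without control replicate 2, control replicate 3 or the 2500 ppm replicates 1 and 3, was 1 without 750 ppm replicate 1 or 2500 ppm replicate 2, and was 44, 8 and 48 without control replicate 1, 750 ppm replicate 2 and 750 ppm replicate 3. Where it was 0, between 1572 and 2819 probe sets had an unadjusted p under 0.05. Without both control replicate 3 and 750 ppm replicate 3 it was 71, with 60 higher and 11 lower.

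Meningeal genes were the group that stood highest at 750 ppm. All 18 were higher, with a median of 1.12, and 17 passed adjusted over the list alone (0 over all genes tested), among them the organic anion transporter gene Slc22a6 at 0.77 (SE 0.15, adjusted p = 0.176). The camera adjusted p was 1.69e-19, with an adjusted p = 0.391 with an estimated correlation. Beside them, 16 of 17 endothelial genes were higher with a median of 0.29 (0.14 without control replicate 3), and 7 passed adjusted over the list alone, such as Emcn at 0.87 (SE 0.20) and Cldn5, a tight junction gene of the blood-brain barrier, at 0.51 (SE 0.13). Their camera adjusted p was 2.88e-06, with an adjusted p = 0.495 with an estimated correlation. Of 17 microglial and macrophage genes, 15 were higher with a median of 0.21 (0.41 without 750 ppm replicate 3) and 6 passed adjusted over the list alone, including the complement gene C1qc at 0.46 (SE 0.10) and Mrc1, a marker of macrophages at the brain's borders, at 1.19 (SE 0.27). That list had a camera adjusted p of 4.28e-05, and an adjusted p = 0.397 with an estimated correlation. Of 14 xenobiotic metabolism genes, 4 passed adjusted over the list alone, Sult1a1, Cyp1b1, Ephx1 (0.36, SE 0.08) and Gsta1 (1.23, SE 0.36), with a list median of 0.19. Its camera adjusted p was 0.00233, with an adjusted p = 0.391 with an estimated correlation, and its fry adjusted p was 0.0247. Of 29 matrix genes, 10 passed higher and 2 lower adjusted over the list alone, with Lama2 at 0.59 (SE 0.12) and Col4a1 at 0.46 (SE 0.10). The matrix list had a median of 0.078, a camera adjusted p of 0.0468 and an adjusted p = 0.598 with an estimated correlation. Its median was 0.12 without control replicate 1 or 3 and 0.18 without 750 ppm replicate 3, and its call was lost without control replicates 2 or 3 and 750 ppm replicates 2 or 3, with an adjusted p of at most 0.143. Pericyte genes had a median of 0.17 and 4 of 13 passed adjusted over the list alone, with Vtn at 0.64 (SE 0.16), a camera adjusted p of 0.0347 and an adjusted p = 0.545 with an estimated correlation. Their call was lost without the same 4 arrays (adjusted p at most 0.149), and the median was 0.10, 0.11, 0.10 and 0.070 without control replicates 1 and 3 and 750 ppm replicates 1 and 2.

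Heat shock genes were slightly higher at 750 ppm, with 13 of 15 above control, a median of 0.10 and 1 passing adjusted over the list alone, Hspb8 at 0.45 (SE 0.10). The camera adjusted p was 0.0328, the adjusted p = 0.391 with an estimated correlation and the fry adjusted p 0.0247. Respiratory chain genes had a median of 0.057 (31 of 37 higher, camera adjusted p = 0.00868, and adjusted p = 0.612 with an estimated correlation), and cholesterol synthesis genes a median of 0.18 (20 of 21 higher, camera adjusted p = 0.0337, and adjusted p = 0.785 with an estimated correlation). In both lists 0 genes passed adjusted over the list alone. The cholesterol median was 0.31 without control replicate 2, and the call was lost without control replicate 3 (median 0.0051, adjusted p = 0.907, with the direction of the test turned) and without 750 ppm replicate 3 (median 0.064, adjusted p = 0.798). With array weights that median was -0.025. The respiratory median was 0.030 and 0.11 without 750 ppm replicates 1 and 3, and its call was lost without control replicate 2 or 750 ppm replicate 2. The heat shock call was lost without control replicate 2 or 750 ppm replicate 3.

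Clock, glial precursor and striatal genes were lower at 750 ppm. Of 16 circadian clock genes, 13 were lower with a median of -0.17 (-0.045 without control replicate 3, where the call was lost with an adjusted p of 0.0515), and 2 passed adjusted over the list alone, Npas2, a partner of the clock protein Bmal1, at -0.34 (SE 0.08) and the nuclear receptor gene Rorb at -0.70 (SE 0.19). Camera gave an adjusted p of 0.000459, and an adjusted p = 0.495 with an estimated correlation. Of 10 oligodendrocyte precursor genes, 9 were lower with a median of -0.15 (-0.23 without control replicate 3) and 3 passed adjusted over the list alone, including Bcas1 at -0.90 (SE 0.21) and Sox10 at -0.43 (SE 0.11), with a camera adjusted p of 0.000710 and an adjusted p = 0.495 with an estimated correlation. Of 15 striatal genes, 12 were lower with a median of -0.43 and 0 passed adjusted over the list alone (camera adjusted p = 0.000504, and adjusted p = 0.598 with an estimated correlation), with Tac1 at -0.43 (SE 0.14) and Foxp1 at -0.44 (SE 0.18). Without 750 ppm replicate 3, in which the mean of the striatal genes was -0.90, their median was -0.018 and the adjusted p 0.706. Markers of excitatory cortical layers had a median of -0.065 (13 of 17 lower, 0 passing, camera adjusted p = 0.0353, and adjusted p = 0.391 with an estimated correlation). That median lay between -0.12 without control replicate 3 and -0.0073 without 750 ppm replicate 3, and was -0.11 and -0.038 without control replicate 2 and 750 ppm replicate 1. The call was lost without control replicates 1 or 3 or 750 ppm replicates 1 or 3.

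Of the 13 lists shifted at 750 ppm, the meningeal, endothelial, microglial, xenobiotic and oligodendrocyte precursor lists kept their call each time 1 array was left out. The others did not: 7 of the 13 remained without 750 ppm replicate 3, 8 without control replicate 3, 9 without control replicate 2, 10 without 750 ppm replicate 2, and 12 without control replicate 1 or 750 ppm replicate 1.

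The comparison of 2500 ppm with 750 ppm asked which transcripts differed between the doses, without the control means. Npas2 was higher at 2500 ppm by 0.79 (SE 0.082, n = 3 against 3, adjusted p = 0.00869), with means of 10.64 (SD 0.11) in controls, 10.29 (SD 0.12) at 750 ppm and 11.08 (SD 0.067) at 2500 ppm. Cplx3 was higher by 1.03 (SE 0.087, adjusted p = 0.00469). The clock gene Nr1d1 was higher by 0.83 (SE 0.13, adjusted p = 0.0398), and the axon guidance ligand gene Efna5 by 1.00 (SE 0.12, adjusted p = 0.0135). C1ql3 fell by 1.58 (SE 0.10, adjusted p = 0.00119) between the doses, but its other probe set, with 0.10 and an adjusted p of 0.565, did not share the direction. Glra2, a glycine receptor subunit of the immature brain, fell by 0.86 (SE 0.094, adjusted p = 0.0126).

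Ttr rose by 4.33 (SE 0.62, adjusted p = 0.0300) between the doses. Arhgef26 rose by 0.83 (SE 0.085, adjusted p = 0.00858), Ap1s3 by 1.12, Mustn1 by 0.92, the muscle-type cytochrome oxidase gene Cox6a2 by 0.83, Dmgdh by 0.78, Emx1, a transcription factor of the dorsal forebrain, by 0.76 (adjusted p = 0.0306) and Clstn2 by 0.62. Nsf, the ATPase that recycles SNARE complexes, fell by 0.63 (SE 0.073, adjusted p = 0.0132, with 1 other probe set passing and 1 at -0.39 with an adjusted p of 0.127) and Pacsin1 by 0.69 (adjusted p = 0.0148). Cdh22, Luzp2, Rasgef1c, Meis2 and Cdh13 fell by 1.01, 0.96, 0.93, 0.92 and 0.88, while other probe sets gave -0.17 for Cdh22 and -0.20 for Luzp2, with adjusted p of 0.678 and 0.350. Clk1 fell by 0.74, Spats2l by 0.67 (another probe set at -0.28, adjusted p = 0.473) and Zfp423 by 0.59 (adjusted p = 0.0238). Other probe sets of Zfp423 gave 0.13, 0.17 and -0.34 with adjusted p of 0.647, 0.382 and 0.140. In total 70 probe sets passed, 33 higher and 37 lower, with 43 named genes. At an unadjusted p under 0.05 there were 2733. After median-centring 48 were higher and 34 lower. The count went to 13 and 30 without 750 ppm replicates 1 and 2, to 731 without 750 ppm replicate 3, to 17, 20 and 36 without 2500 ppm replicates 1, 2 and 3, and to 39 and 32 without control replicates 1 and 2. It was 1149 without both control replicate 3 and 750 ppm replicate 3. Of the 24 named genes, C1ql3, Luzp2, Cplx3, Npas2 and Arhgef26 passed whichever array was left out, while 6 of 24 passed without 750 ppm replicate 1 and 7, 11 and 12 without 2500 ppm replicates 1, 2 and 3, 16 without 750 ppm replicate 2 or control replicate 2, and 17 and 21 without control replicates 1 and 3.

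**Figure D3:**
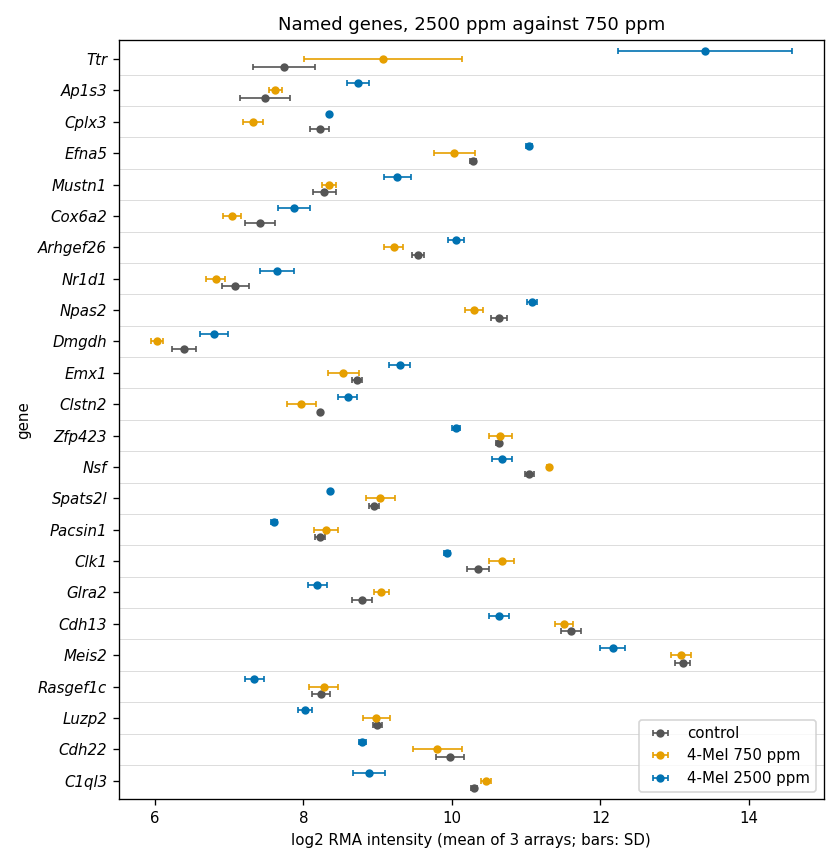
Group means of the log2 RMA intensity of the 24 genes named for 2500 ppm against 750 ppm, with bars of 1 SD over 3 arrays. Npas2 was at 10.29 at 750 ppm and 11.08 at 2500 ppm, with 10.64 in controls between them.

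Choroid plexus and clock genes were higher at 2500 ppm than at 750 ppm. All 10 choroid plexus genes were higher, with a median of 0.59 (0.89 without 2500 ppm replicate 3), and 7 passed adjusted over the list alone against 1 over all genes tested. Sostdc1 was 2.40 higher (SE 0.57, adjusted p = 0.140) and the ependymal gene Tmem212 0.53 higher (SE 0.12, adjusted p = 0.117). The camera adjusted p was 4.17e-08, with an adjusted p = 0.943 with an estimated correlation. Of 16 clock genes, 12 were higher with a median of 0.18 (0.084 without 750 ppm replicate 1), and 5 passed adjusted over the list alone against 2 over all genes tested, Npas2 and Nr1d1, with Dbp at 0.38 (SE 0.06, adjusted p = 0.0566). Their camera adjusted p was 0.00221, with an adjusted p = 0.943 with an estimated correlation. Oligodendrocyte precursor genes had a median of 0.16 (0.092 without 2500 ppm replicate 1) with 2 of 10 passing adjusted over the list alone, Bcas1 at 0.87 (SE 0.21) and Sox10 at 0.40 (SE 0.11), and myelinating oligodendrocyte genes a median of 0.22 with 0 of 10 passing. Both had a camera adjusted p of 0.0406 and an adjusted p = 0.943 with an estimated correlation.

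Striatal, meningeal and GABA genes were lower at 2500 ppm than at 750 ppm. Of 15 striatal genes 13 were lower, with a median of -0.68, and 1, Tac1 at -0.67 (SE 0.14, adjusted p = 0.0906), passed adjusted over the list alone (camera adjusted p = 0.0302, and adjusted p = 0.943 with an estimated correlation). The median was -1.20 without 750 ppm replicate 3 and -0.46 without 750 ppm replicate 1 or 2500 ppm replicate 1, and the call was lost without control replicate 3, 750 ppm replicates 1 or 2 or 2500 ppm replicate 1. Of 11 genes of GABA synthesis and transport 10 were lower, with a median of -0.26, while the only member to pass adjusted over the list alone was higher, the chloride importer gene Slc12a2 at 0.32 (SE 0.08, adjusted p = 0.176). The GABA synthesis genes Gad2 and Gad1 were at -0.83 (SE 0.31) and -0.74 (SE 0.29), and the list had a camera adjusted p of 0.0406, an adjusted p = 0.943 with an estimated correlation, and a median of -0.16 without 750 ppm replicate 1. Its call was lost without control replicates 2 or 3, 750 ppm replicates 1 or 2, or 2500 ppm replicates 1 or 2 (camera adjusted p at most 0.199). Whether the GABA genes fell with the striatal list, at -0.68 in the same comparison, was not tested. Of 18 meningeal genes 17 were lower, with a median of -0.24 (-0.16 without 750 ppm replicate 1, -0.12 without 2500 ppm replicate 1, camera adjusted p = 0.0406, and adjusted p = 0.943 with an estimated correlation). Respiratory chain genes had a median of -0.061 (-0.032 without 750 ppm replicate 1, camera adjusted p = 0.0302) and ribosomal protein genes a median of -0.038 (camera adjusted p = 0.0406), and 0 genes of these last 3 lists passed adjusted over the list alone. With an estimated correlation, the respiratory and ribosomal lists had an adjusted p = 0.943. Only the choroid plexus and clock lists, of the 9 shifted, kept their call whichever array was left out: 2 of the 9 remained without 2500 ppm replicate 1 or 750 ppm replicate 2, 4 without control replicates 2 or 3 or 750 ppm replicate 1, 6 without 750 ppm replicate 3 or 2500 ppm replicate 2, and 8 without control replicate 1 or 2500 ppm replicate 3.

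Of the 5 lists of channels, receptors and activity genes given here, none passed camera between the doses. The camera adjusted p was 0.913 for potassium channels, 0.759 for ionotropic glutamate receptors, 0.521 for GABA receptors, 0.551 for sodium channels and 0.913 for immediate early genes. Kcna4 fell by 0.42 (SE 0.06, adjusted p = 0.0391), with 1 of 27 potassium channel genes higher and 3 lower adjusted over the list alone, and Grik2 was at -0.95 (SE 0.17, adjusted p = 0.0668), past the threshold adjusted over the list alone. Gabra2 was at -0.91 (SE 0.18, adjusted p = 0.0806), the 1 of 11 GABA receptor genes to pass adjusted over the list alone. Bdnf, the activity-regulated neurotrophin, was at -0.78 (SE 0.14, adjusted p = 0.0683), the 1 of 19 immediate early genes to pass adjusted over the list alone, and Fos was at -1.003 (SE 0.56, adjusted p = 0.514). Klf9 was at 0.58 (SE 0.14, adjusted p = 0.140).

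A linear change with dose was tested over all 9 arrays. Of the 104 probe sets that passed, 30 rose and 74 fell, and they carried 62 named genes, 16 higher and 46 lower. Of these, 92 also passed for 2500 ppm against control. The count went to 51, 25 and 68 without control replicates 1, 2 and 3, to 188 and 193 without 750 ppm replicates 1 and 3, and to 2, 0 and 26 without 2500 ppm replicates 1, 2 and 3, where the count of 0 stood beside 2795 at an unadjusted p under 0.05. Median-centring gave 38 higher and 60 lower.

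The probe sets that passed at both doses numbered 0 in limma, with 2202 and 3478 at an unadjusted p under 0.05 at 750 and 2500 ppm. Across all 21729 probe sets, which are not independent replicates, the changes at both doses correlated with r = 0.583 and had the same sign in 67.7%. Both use the same 3 control arrays, and 100 simulations of unchanged groups with shared controls gave r = 0.499, between 0.463 and 0.527, and the same sign in 66.6%. The simulated probe sets varied independently, while the first principal component of the real arrays held 35.6% of the variance. The simulated range therefore leaves out variation that probe sets share, and does not decide whether the doses share a response. The observed covariance was 0.0216 against a simulated 0.00610. With 3 controls, the control arrays cannot be divided into separate sets of at least 2 for each comparison, so the share of r owed to common controls was only simulated. Without 750 ppm replicate 3, r was 0.370.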

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

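The tests of a single array, of a lower share of neural cells, of control replicate 3 alone and of fewer neurons of every kind were chosen after the result was seen, as were the fits with a tissue list as a covariate.

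Of the 70 probe sets that passed for 2500 ppm against 750 ppm, 21 lay on opposite sides of control at the doses, with an unadjusted p under 0.05 at each. They were chosen by that contrast, so its p is no separate test of them. The clock gene Npas2 was at -0.34 at 750 ppm and 0.45 at 2500 ppm, a difference of 0.79 (SE 0.082). The exchange factor gene Arhgef26 was at -0.32 and 0.51, the matrix protein gene Ccn2 at -0.29 and 0.28, the calsyntenin gene Clstn2 at -0.26 and 0.37, and the calcium release channel gene Ryr2 at -0.35 and 0.25. In the other direction, the glycine receptor gene Glra2 was at 0.26 and -0.59, the kinase gene Clk1 at 0.32 and -0.42, the sorting receptor gene Sorcs3 at 0.31 and -0.28, the deacetylase gene Hdac1 at 0.25 and -0.26, and 1 probe set of Nsf at 0.26 and -0.37.

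Among the 9313 dim probe sets left out of the comparisons, 11 were higher than control at 2500 ppm and 1 at 750 ppm when all were fitted with limma. At 2500 ppm they included the phosphatase subunit gene Ppp1r3b at 1.12, the ferritin receptor gene Scara5 at 0.99, Mrln at 0.71, Myo5c at 0.70, Tmem252 at 0.57, the myelin gene Ermn at 0.51 and Defb1 at 0.45. The 1 probe set at 750 ppm has no symbol and was 0.74 higher. Another 18 were lower at 2500 ppm, among them Klhl41 at -1.39, Rasgrp1 at -0.93 and Lhx9 at -0.88.

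Choroid plexus genes were higher at 2500 ppm, by a median of 0.56 over 10 genes, led by Ttr. A single array does not explain this, since the median without 2500 ppm replicate 1 was 0.496. A second list of 13 other choroid plexus genes had a median of 0.22, above 99.9% of 10000 random lists of its size (0.11 at 750 ppm, where the first list was at -0.0040). Random lists hold unrelated genes, so this rank does not measure the spread between arrays. The mean of the second list was -0.039, -0.24 and -0.38 in the controls. It was 0.074, 0.0053 and -0.071 at 750 ppm and 0.29, 0.31 and 0.050 at 2500 ppm. More choroid plexus tissue in the dissected samples is a candidate explanation. Ttr went from 7.74 to 13.40, Enpp2 from 9.26 to 10.08 and Sostdc1 from 6.07 to 9.12; 2 of the 10 genes stand in another list, and 0 of them had a control mean above the median of all genes. A response of the choroid plexus to 4-MeI stays open and was not tested.

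Meningeal genes were higher at both doses, with medians of 1.12 and 0.83 over 18 genes. Control replicate 3, where they were lowest, is not the whole source, since without it the medians were 0.817 and 0.532. A lower share of neural cells would raise all other cells alike. The meningeal median exceeded the endothelial, pericyte and microglial medians by at least 0.555 (SE 0.107 between member genes). That SE does not measure the spread between arrays, so how much of the rise a lower share of neural cells gives stays open. A second list of 28 meningeal genes had medians of 0.584 and 0.488, above all of 10000 random lists. Random lists hold unrelated genes, so this rank does not measure the spread between arrays. The mean of the second list was -0.034, -0.33 and -0.66 in the controls. It was 0.30, 0.18 and 0.18 at 750 ppm and -0.041, 0.13 and 0.28 at 2500 ppm, where it overlapped the controls. Meningeal tissue left on the cortex of exposed pups is a candidate explanation. Ptgds went from 11.83 in controls to 13.23 and 12.99, Igf2 from 10.73 to 11.96 and 11.94, and Col3a1 from 10.31 to 11.57 and 11.19; 2 of the 18 genes stand in another list, and 6 had a control mean above the median of all genes. A growth of meninges or vessels under exposure stays open and was not tested.

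Striatal genes were lower at 2500 ppm, by a median of -1.10 over 15 genes. Fewer neurons of every kind would lower cortical markers too, but the striatal median minus that of excitatory layer genes was -0.984 (SE 0.208 between member genes). That SE does not measure the spread between arrays, so this explanation is not decided. A second list of 17 striatal genes had a median of -0.196, with 3 of 17 higher and below all of 10000 random lists. Random lists hold unrelated genes, so this rank does not measure the spread between arrays. The mean of the second list was 0.34, 0.12 and 0.17 in the controls and -0.43, -0.094 and -0.20 at 2500 ppm. It was also low in 750 ppm replicate 3, at -0.40 against 0.26 and 0.24 in the other arrays of its group. Less striatum in the dissected tissue is a candidate explanation. Foxp1 went from 12.41 to 12.03, Pde10a from 11.35 to 10.76 and Rarb from 10.98 to 8.96; 5 of the 15 genes stand in another list, and 8 had a control mean above the median of all genes. An effect of 4-MeI on striatal neurons stays open and was not tested.

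With the mean of the striatal list as a covariate, Ttr, C1ql3 and Luzp2 still passed at 2500 ppm on the probe sets that had passed. Ttr was at 6.53 (SE 0.73, adjusted p = 0.0379 in limma), C1ql3 at -1.52 (SE 0.13, adjusted p = 0.0134) and Luzp2 at -1.15 (SE 0.085, adjusted p = 0.0107). Cdh13 was at -0.80 (SE 0.10, adjusted p = 0.0650, against -0.97 and SE 0.10 without the covariate) and no longer passed, and the cause was not tested. With the meningeal list as a covariate none of the 3 passed at 2500 ppm, with Ttr at 6.40 (SE 1.00, adjusted p = 0.294), C1ql3 at -1.39 (SE 0.17, adjusted p = 0.208) and Luzp2 at -0.86 (SE 0.15, adjusted p = 0.393). With the choroid plexus list as a covariate, Luzp2 was at -0.92 (SE 0.23, adjusted p = 0.740), Ttr, itself a member of that list, was at 2.51 (SE 0.93) instead of 5.67 (SE 0.62), and C1ql3 at -1.35 (SE 0.25) instead of -1.42 (SE 0.10). C1ql3 no longer passed (adjusted p = 0.605), with a similar change and a larger SE, and the mean of this list was higher in each 2500 ppm array than in any other array.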

How the results depend on the processing

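The alternatives that left out 2 arrays together or took a tissue list as a covariate were chosen after seeing the data, and all others before the data were examined. Counts of probe sets are given in the order 750 ppm, 2500 ppm and 2500 against 750 ppm, then dose trend, with 2, 149, 70 and 104 reported.

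Filters, scaling and variance changed these counts by at most 1.5 times: no filter gave 170 at 2500 ppm, of which 141 were among the 149, median-centring 166 (129 shared), a second quantile normalization 145 (127 shared), and an intensity trend with robust variance 199 (144 shared). Array weights gave 340, 1495, 721 and 543 and held all calls reported. Fits of only the groups compared gave 1, 481 (103 higher and 378 lower) and 14. An unadjusted p under 0.05 with a fold of at least 1.5 gave 232, 450, 254 and, for the trend, 23. An adjusted p under 0.1 gave 585, 205 and 405 at 2500 ppm, between the doses and for the trend. With 1 probe set per gene the counts were 1, 66, 40 and 36, from fewer features tested. With the replicate number as a block they were 36 between the doses and 67 for the trend. Residual correlations ranged from -0.209 to 0.312 for arrays with the same number and from -0.335 to 0.192 for arrays with different numbers. With 3 arrays per group, these correlations do not decide whether the numbers mark pairs or a batch.

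Without control replicate 3 and 750 ppm replicate 3 the first 3 counts were 71, 263 and 1149. With the striatal list as a covariate the counts were 0, 8, 27 and 1. With the meningeal list they were 0, 0, 43 and 94, and with the choroid plexus list 0, 0, 0 and 0. Where a covariate gave 0, between 649 and 2466 probe sets had an unadjusted p under 0.05 in limma, against 1086 expected by chance. The 649 at 750 ppm with the meningeal list lay under that number. So did the 1046 between the doses with the choroid plexus list. Leaving out 1 array gave 0 to 48, 9 to 466, 13 to 731 and 0 to 193. An arm of 2 arrays then borrows its spread from the other groups.

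Of the lists, 13, 10 and 9 were shifted. With 1 array left out these counts ranged from 9 to 16, from 8 to 12 and from 2 to 11. Between the doses, 1 list was shifted with the lowest 50% left out, 5 after median-centring and 4 in fits of only the groups compared. At 750 ppm, 5 were shifted with array weights and 8 without both arrays. Camera with an estimated correlation gave 0, 0 and 0, with 5, 1 and 1 of 46 lists at an unadjusted p under 0.05, and fry gave 2, 2 and 0, with 10, 12 and 4. The direction turned for cholesterol synthesis at 750 ppm, with medians of -0.025 with array weights and -0.081 without both arrays, against 0.18. With 1 array left out this median ranged from 0.0051 without control replicate 3, where camera pointed down, to 0.31 without control replicate 2. Klf9, which had not passed, went to -0.039 at 2500 ppm with array weights. Other probe sets gave 0.12 and 0.10 for C1ql3 at 2500 ppm and between the doses, and 0.13 and 0.17 for Zfp423 between the doses, where another was at -0.34. The correlation of both doses ranged from 0.370 to 0.669 with 1 array left out, and stayed between 0.563 and 0.591 under other filters and scalings. For these changes the cause was not tested unless stated. A sex-linked covariate was not run, as the sex-linked genes measured do not form separate levels. Signal over background limits the genes near a log2 value of 6.35, below which probe sets were left out of the reported comparisons and changes are compressed.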

Other observations

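The list tests and the splits of the arrays were set before the data were examined, while the choice of which lists to describe in this part and the tests of Xist and of the control probe sets were made after results were seen.

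Stress hormone and small heat shock genes showed single-gene differences at 2500 ppm. Cryab, a chaperone of the small heat shock family, was 0.41 higher (SE 0.06, adjusted p = 0.0287 in limma) and Hspb1 0.55 higher (SE 0.12, adjusted p = 0.0940), and both passed adjusted over the list alone, with a camera adjusted p of 0.130 and a fry adjusted p of 0.0204 for the 15 genes. Of 19 glucocorticoid responsive genes, 4 were higher adjusted over the list alone, including Sult1a1 and the kinase gene Sgk1 at 0.45 (SE 0.098, adjusted p = 0.0857), with a camera adjusted p of 0.125. The axon guidance gene Efna5 rose by 0.76 (SE 0.12, adjusted p = 0.0323), 1 of 34 genes of its list to pass over all genes tested. Markers of GABAergic interneurons had a median of -0.20 and a camera adjusted p of 0.0595, with 0 of 16 passing adjusted over the list alone, 2 at an unadjusted p under 0.05, Gad2 at -1.09 (SE 0.31) and Dlx1 at -0.77 (SE 0.26). In the same comparison the striatal list had a median of -1.10, and whether the interneuron markers fell with it was not tested.

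Genes that handle histamine, another imidazole compound, did not shift as a group, with a camera adjusted p of 0.924 at 2500 ppm and 0.452 at 750 ppm over 8 genes. The histamine receptor gene Hrh3 was at -0.38 (SE 0.093, adjusted p = 0.198) at 750 ppm, where it passed adjusted over the list alone. Between the doses Hrh3 was at 0.40 (SE 0.093, adjusted p = 0.135) and the organic cation transporter gene Slc22a3 at 0.86 (SE 0.25, adjusted p = 0.247), and both passed adjusted over the list alone. Syn2, a synapsin, was at -0.63 (SE 0.14, adjusted p = 0.126) between the doses and passed adjusted over its list alone.

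The labels give no sex. On the brightest probe set, Xist was at 12.17, 12.31 and 12.59 in the controls, 11.40, 12.39 and 11.60 at 750 ppm and 11.52, 11.61 and 11.51 at 2500 ppm. The difference at 2500 ppm was -0.81 (SE 0.22, adjusted p = 0.131 in limma), and the other Xist probe sets gave -0.51, -0.57 and -0.49. Uty, a Y-linked gene, lay between 10.02 and 10.42 on every array on its brighter probe set. Its other probe set lay between 5.66 and 5.97 on every array and was among the dim probe sets left out. The probe sets of Uty therefore differ, and whether its RNA was present in each pup was not decided. The AFFX control probe sets gave 2, 1 and 1 of 57 at an unadjusted p under 0.05 in the 3 comparisons and 0 after adjustment.

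Other splits of the same arrays were counted. For 2500 ppm against control, 1 of the 10 splits of the 6 arrays, the real one, gave as many as 149 probe sets, and the highest of the others gave 0. Between the doses it was again 1, with 70 against 0. At 750 ppm, 2 of the 10 splits gave as many as 2 probe sets, and the highest other gave 3. For lists, 1 split gave as many as 13 at 750 ppm (highest other 11), 2 gave as many as 10 at 2500 ppm (highest other 14), and 3 gave as many as 9 between the doses (highest other 11). Every other split also gave shifted lists, at least 2 at 750 ppm, 4 at 2500 ppm and 4 between the doses. Camera at the preset correlation thus called lists in mixed groups too, and the number of lists alone does not mark a difference by dose. With 10 splits, no share under 0.05 can be reached. For the dose trend, 2 of 100 regroupings of the 9 arrays, the real one included, gave as many as 104 probe sets. That share is under the 0.05 set beforehand. The other regrouping, also at 104, kept the 2500 ppm arrays together and mixed the control and 750 ppm arrays. The count therefore does not tell a linear trend from a difference of the 2500 ppm arrays alone.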
